A study of Mus musculus with 20 samples.

How the data were processed

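Gene expression was measured in the striatum and the liver of 8 week old male mice on a C57BL/6 background. The 4 groups were wild-type striatum, Mecp2-null striatum, wild-type liver and Mecp2-null liver, with 5 arrays each and 20 arrays in all. Per the labels, every array held a separate biological replicate of its group, and the livers came from the animals whose striatum was taken. Groups and replicate numbers were read from the sample titles. The RNA was extracted with TRIzol, treated with DNase and cleaned on a column, and 100 ng of total RNA was amplified and hybridised to a 1-colour Affymetrix exon array.

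The deposited values were log2 expression values for 23332 gene-level probe sets, which the authors made with Affymetrix Power Tools and the robust multi-array average (RMA), per the submitters' processing notes, on build mm9. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a set by median polish. The versions of these tools, the class of probe sets and any filter were not given in the sources used here. Array medians lay between 7.03 and 7.10 in the striatum and between 6.22 and 6.34 in the liver, so whether the 2 tissues were normalized together or apart stayed unknown. A shift common to one tissue cancels in a genotype comparison within that tissue and in the interaction, while it moves each value of the comparison between tissues. No raw intensities were used here, so no probe set could be tested against background. The number of arrays limits the precision of each mean.

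Probe sets were named from the platform annotation. Of the probe sets, 14996 had 1 gene symbol, 1019 had several and 7317 were unnamed here, and no gene was named from a probe set with several symbols. The Entrez identifiers of 14941 of the named probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. The named probe sets stood for 14860 genes, and where one of the 135 genes with more than 1 probe set was tested in a list, the probe set with the highest mean over the arrays of the comparison represented it. The RefSeq table belongs to another assembly than the arrays, so it was used for names and for the order of neighbouring genes, and no coordinates are given. A relation between gene length and expression was not analysed here for the same reason. No probe set carried the name Mecp2 (0 of 23332), so the targeted gene was not analysed here and the genotype labels rest on the titles.

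All tests used limma (3.58.1) in R (4.3.3). Figures were drawn with matplotlib (3.10.9) in Python (3.11.15). Mecp2-null was compared with wild type within each tissue from the 10 arrays of that tissue. The interaction, which is the striatal genotype difference minus the hepatic one, used all 20 arrays, and wild-type striatum was compared with wild-type liver on 10 arrays. Linear models were fitted to the log2 values and moderated with empirical Bayes, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all 23332 probe sets. A probe set was called at an adjusted p under 0.05. Values are means ± SD over 5 arrays, differences are log2 differences with the standard error (SE) of the model, and a fold is the difference raised from the log2 scale.

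Gene lists for cell types, pathways and the neighbourhood of Mecp2 were written down before the data were examined, as were the design, the rule for named genes and most alternatives. Each list with at least 5 measured genes was tested with camera at its preset correlation of 0.01 between genes, and adjusted over 28 lists in the striatum and 24 in the liver. The test was repeated with the correlation estimated from the arrays. Counts of list members are given after adjustment over all probe sets and adjusted over the list alone. An erythroid list had too few measured genes to be tested. The text names, for each genotype comparison, the 12 largest rises and the 12 largest falls among called probe sets with 1 symbol whose higher group lay at or above the median of the tissue. It names 5 genes each way for the interaction and 10 each way between tissues. In a list it names up to 4 called members by smallest p, or up to 2 members with the smallest p where none was called. Genes named outside this rule are said to be chosen after their values were seen.

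The fit and the list test were checked on simulated values with changes planted among 23332 probe sets, drawn with the means and spreads of the real ones. In the simulated striatal comparison, 24 of 50 changes of 0.5 log2 units, 90 of 100 changes of 1 unit and 47 of 50 changes of 2 units were recovered, with 7 false calls among 168. In the simulated hepatic comparison the numbers were 30 of 50, 88 of 100 and 50 of 50, with 5 false calls among 173. A list with each member shifted by 0.5 log2 units was called in both, with 0 other lists. Most lists called in the real data had medians nearer 0, so this does not show how small a shift the list test finds. The simulated genes varied independently, with 1 spread per probe set over both tissues. Real list members varied together, with an estimated correlation of up to 0.83 (oligodendrocyte and myelin genes). The simulation therefore cannot show how often the preset correlation calls a list by chance in these data. No 2 of the 190 pairs of arrays held identical values.

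Alternatives were the removal of dim probe sets, an intensity trend with robust moderation, a repeated quantile normalization, median-centred arrays, 1 fit to all 20 arrays, array weights, the replicate number as a block, the omission of each array in turn, the restriction to probe sets with 1 symbol, a minimum change of 1.2-fold, and for lists an estimated correlation and all probe sets of a gene. After the data were seen, 2 more were added for the striatum. One left out the 2 Mecp2-null arrays with high cortical markers, and the other used the cortical marker mean as a covariate. Counts were also compared with those from 100 splits of the same arrays, the real one included.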

Results

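MeCP2 is a chromatin protein that binds methylated DNA, and its loss in mice models Rett syndrome. The study asked how expression changes without MeCP2 in the striatum, a brain region made mostly of GABAergic medium spiny neurons, and used liver as a non-neuronal tissue. Mecp2-null males with the Bird allele, already symptomatic at 8 weeks, were compared with wild-type littermates in both tissues, with 5 arrays per group. Arrays of one group correlated at 0.983 or above across probe sets, and a striatal and a hepatic array correlated between 0.711 and 0.738. The array annotation paired no probe set with Mecp2, so the deleted gene could not serve as a check of the genotype labels.

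Wild-type striatum and liver differed as these tissues should by their known marker genes. Genes are ranked here among probe sets with 1 symbol. Among the 10 largest differences toward striatum were the glutamate receptor subunit Gria2 (11.69 ± 0.07 against 2.93 ± 0.05, SD, n = 5), the neuropeptide precursors Penk (13.48 ± 0.04 against 4.90 ± 0.28) and Tac1 (11.42 ± 0.13 against 3.07 ± 0.09), and the synaptic protein Snap25 (12.91 ± 0.04 against 4.71 ± 0.11). Elmod1, Cnksr2, Spock3, Lgi1, Calb1 and Negr1 completed them, with log2 differences between 7.84 and 8.60. Toward liver the largest were the tryptophan dioxygenase Tdo2 (12.73 ± 0.11 against 3.57 ± 0.15), the fatty acid-binding protein Fabp1 (12.86 ± 0.14 against 3.79 ± 0.11), Serpina6, the fibrinogen chain Fgg, Ces1c, Slco1a1, Ugt2b1, Cyp2e1, Orm1 and Pon1. The 20 genes kept their calls in each alternative tried. In all, 19622 probe sets were called (84.1%), 15266 of them higher in striatum and 4356 higher in liver. The median probe set was 0.59 log2 units higher in striatum. With each array centred on its median the split was 6528 higher in striatum and 10912 higher in liver, and with the arrays quantile-normalized again it was 7930 and 8924. Over the alternatives the difference of Gria2 went from 8.75 to as low as 7.95, a larger move than 0.59. The direction of small differences between tissues therefore depends on the scaling, and 0.59 is not the upper limit of those affected.

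In the striatum, 57 probe sets were called between Mecp2-null and wild type, 30 higher and 27 lower in Mecp2-null, mostly by less than 2-fold. The largest rise was in Irak1, a kinase of interleukin-1 and Toll-like receptor signalling whose gene lies next to Mecp2, from 7.92 ± 0.09 to 9.03 ± 0.11 (SD, n = 5; 2.16-fold, adjusted p = 0.00021). Crhbp, which binds corticotropin-releasing hormone, rose by 0.86 ± 0.10 log2 units (SE; adjusted p = 0.0074), and the transmembrane protein gene Dlk1 by 0.82 ± 0.12 (adjusted p = 0.025). The potassium channel gene Kcnh7 rose by 0.82 ± 0.09 (adjusted p = 0.0044). The cell adhesion gene Cdh4 (R-cadherin) rose by 0.65, the axon guidance ligand Efna5 by 0.57 and the reelin adaptor Dab1 by 0.51, the last from 10.06 ± 0.07 to 10.57 ± 0.06. Dab1 had 1 other probe set, dimmer over the striatal arrays, whose value is not given here. Tshz1, Smug1, Pnck, Sox1ot and Arhgap6 rose by between 0.56 and 0.68. The largest fall was in Stc1, a secreted glycoprotein, from 7.91 ± 0.16 to 6.86 ± 0.39 (2.08-fold, adjusted p = 0.042). The histamine H3 receptor gene Hrh3 went from 10.39 ± 0.08 to 9.82 ± 0.11 (adjusted p = 0.0044), the purinergic receptor gene P2ry1 changed by -0.58 ± 0.09 (SE), the nucleoside transporter gene Slc29a1 by -0.50 ± 0.07 and the magnesium transporter gene Slc41a1 by -0.54 ± 0.08. Cd72 (-0.83), Myo3b (-0.79), Thbs3 (-0.70), Cpne9 (-0.65), Ecel1 (-0.52), Mal2 (-0.38) and Trib2 (-0.36) were also lower. In each of the 24 genes all 5 Mecp2-null arrays lay beyond all 5 wild-type arrays. The genes were selected on these same arrays, so this separation is no separate evidence.

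**Figure D1:**
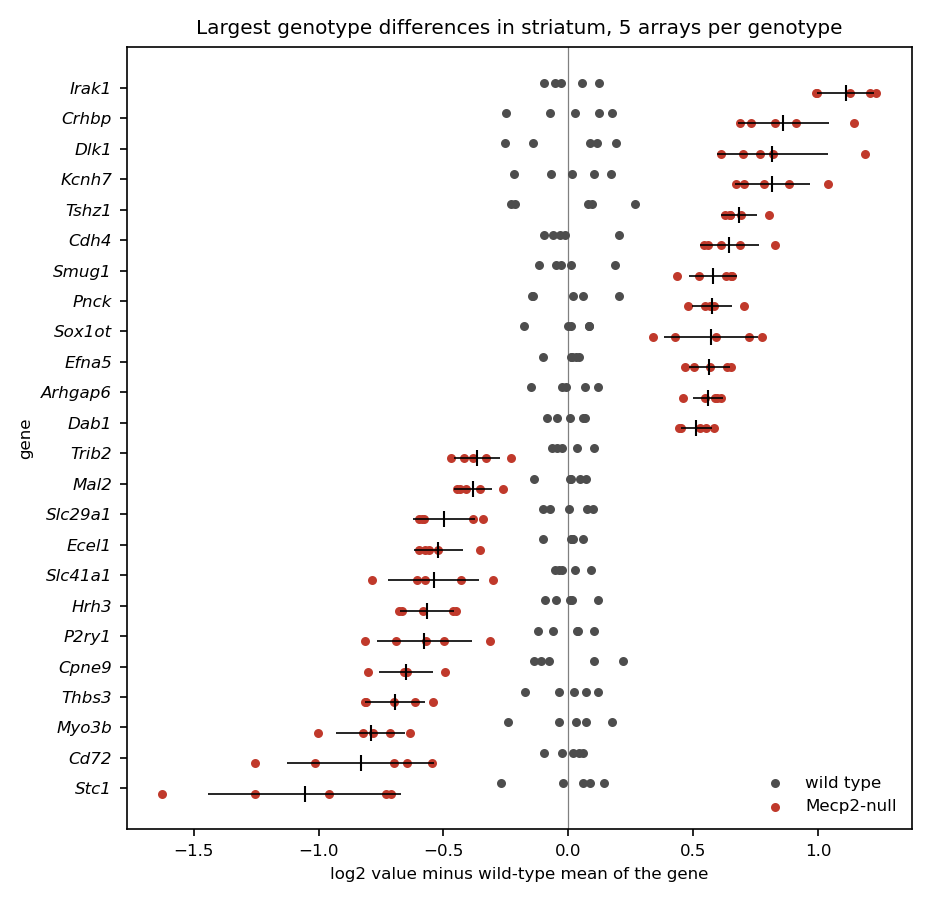
Log2 values of the 24 named striatal genes, each minus the wild-type mean of that gene, for 5 wild-type arrays (grey) and 5 Mecp2-null arrays (red), with the Mecp2-null mean and SD in black. Irak1 stands highest at 1.11 and Stc1 lowest at -1.06, and the genotypes do not overlap in any of the 24, which were selected on these same arrays.

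The 57 probe sets comprised 46 with 1 symbol, 4 with several and 7 unnamed here. Their median absolute change was 0.57 log2 units, and 2 passed 2-fold (Irak1 and Stc1). At an unadjusted p under 0.05 there were 2473 probe sets, against 1167 by chance. With any 1 array left out the count lay between 28 and 54, and 14 of the 24 named genes stayed called each time, Irak1, Crhbp, Kcnh7, Efna5, Dab1 and Hrh3 among them, while Dlk1, Tshz1, Sox1ot, Stc1, Cd72, P2ry1, Slc41a1, Slc29a1, Mal2 and Trib2 did not. In every alternative tried 2 of the 24 stayed called, Irak1 and Hrh3, since Crhbp, Kcnh7, Efna5 and Dab1, for example, lost the call with the replicate number as a block (10 probe sets called) and Cdh4 and Myo3b with the cortical covariate. The count was 143 without dim probe sets, 90 after repeated quantile normalization and 99 in 1 fit to all 20 arrays. Without the 2 Mecp2-null arrays that carried high cortical markers, described next, 53 probe sets were called, 33 of them shared with the 57, and with the cortical marker mean as a covariate 27, of which 21 were shared. Of the 24 named genes, 7 were not called without the 2 arrays, with log2 differences of 0.69 for Dlk1, 0.71 for Tshz1, 0.54 for Pnck, 0.45 for Sox1ot, -0.46 for P2ry1, -0.43 for Slc29a1 and -0.37 for Mal2.

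Markers of neighbouring brain regions differed between the striatal arrays. Cortical excitatory neuron markers were higher in Mecp2-null striatum (10 of 11 genes, median 0.43, camera adjusted p = 6.2e-05), though none was called over all genes and 2 passed when adjusted over the list alone, Mef2c (0.30 ± 0.05, SE) and Cux2 (0.43 ± 0.09). The adjusted p was 0.48 with an estimated correlation. Most of the shift came from replicates 4 and 5, whose list means lay 1.47 and 1.29 log2 units above the wild-type mean, while the other Mecp2-null arrays lay between -0.14 and 0.40. The vesicular glutamate transporter Slc17a7, chosen after its values were seen, read 11.10 and 10.92 in these arrays, between 7.38 and 9.10 in the other Mecp2-null arrays and at most 8.38 in wild type. Thalamic and septal markers followed the same arrays (0.79 and 0.54; list adjusted p = 0.0050, and 0.48 with an estimated correlation), with Tcf7l2 at 0.21 ± 0.08 and Trpc4 at 0.43 ± 0.19. Without these 2 arrays the adjusted p was 0.099 for the cortical and 0.37 for the thalamic list.

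Markers of medium spiny neurons were lower in the same 2 arrays. General medium spiny neuron markers fell as a list (16 of 20 genes lower, median -0.11, adjusted p = 0.030, and 0.72 with an estimated correlation), with replicates 4 and 5 at -0.37 and -0.26 and the other 3 Mecp2-null arrays between 0.01 and 0.03. Without replicates 4 and 5 the adjusted p was 0.44. The list also lost its call after repeated quantile normalization, with median-centred arrays and with array weights. It was lost too with wild-type replicate 4 or 5 or Mecp2-null replicate 4 or 5 left out singly (adjusted p up to 0.20). None of its members was called. Ptpn5, a striatum-enriched phosphatase, stood at -0.22 ± 0.09 and Foxp2 at 0.13 ± 0.05. Markers of the D1 class (adjusted p = 0.060) and the D2 class (adjusted p = 0.10) did not pass, and the dopamine receptor Drd2 stood at -0.18 ± 0.10 (SE, adjusted p = 0.55). In the D1 list 1 of 9 genes, Slc35d3, passed when adjusted over the list alone (-0.52 ± 0.14). Without replicates 4 and 5 Slc35d3 stood at -0.31, Ptpn5 at -0.0774, Drd2 at -0.0206 and Foxp2 at 0.16.

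Immediate early and activity-regulated genes, which neurons induce on firing, rose as a list in Mecp2-null striatum (20 of 23 genes higher, median 0.37, adjusted p = 1.2e-05). The adjusted p was 0.48 with an estimated correlation, and none was called over all genes, while 3 passed when adjusted over the list alone. Nptx2, a synaptic pentraxin, stood at 0.45 ± 0.09 and Jun at 0.37 ± 0.08. The list mean ranged from -0.22 to 0.59 over the Mecp2-null arrays, with 4 of 5 above all wild-type arrays. Without the 2 arrays high in cortical markers the median was 0.12 and the adjusted p 0.026, while the list mean differed by 0.19 ± 0.24 (SE) between the arrays that remained.

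**Figure D2:**
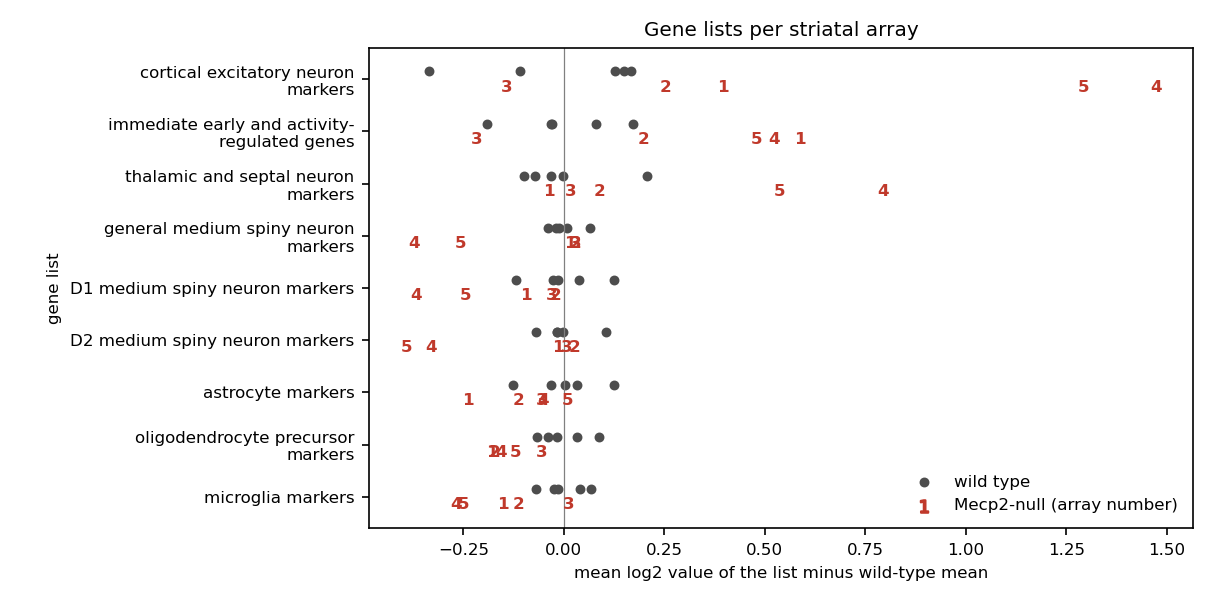
Mean log2 value of 9 gene lists in each striatal array, minus the wild-type mean; grey points are the 5 wild-type arrays and red digits the 5 Mecp2-null arrays by replicate number. Replicates 4 and 5 stand apart in cortical markers (1.47 and 1.29) and in general medium spiny neuron markers (-0.37 and -0.26).

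Several glial lists were lower in Mecp2-null striatum by small amounts. Microglia markers fell most broadly (17 of 18 genes lower, median -0.14, adjusted p = 5.6e-06, and 0.48 with an estimated correlation). Of these, 7 passed when adjusted over the list alone, led by Fcrls (-0.32 ± 0.06) and the complement subunit C1qb (-0.29 ± 0.06). The fall was largest in replicates 4 and 5 (-0.27 and -0.25, against -0.15 to 0.01 in the others), and without them the median was -0.0694 and the adjusted p 0.025. Oligodendrocyte precursor markers fell (7 of 9 lower, median -0.20, adjusted p = 0.0034, and 0.48 with an estimated correlation), with 5 lower and 1 higher over the list alone, among them Vcan at -0.32 ± 0.07 and Neu4 at -0.30 ± 0.07. Astrocyte markers fell too (13 of 19 lower, median -0.10, adjusted p = 0.023, and 0.58 with an estimated correlation), 3 of them over the list alone, with S100b at -0.36 ± 0.08 and Aldoc at -0.17 ± 0.04. None of these genes was called over all probe sets, and the astrocyte list lost its call after repeated quantile normalization and with any of 4 single arrays left out (adjusted p up to 0.16). Without replicates 4 and 5 the astrocyte median was -0.16 (adjusted p = 0.00092) and the precursor median -0.19 (adjusted p = 0.016). Proliferation genes passed upward (median 0.04, adjusted p = 0.036, and 0.58 with an estimated correlation), with Mki67 at 0.43 ± 0.12, and lost the call without replicates 4 and 5 (adjusted p = 0.29), with array weights and with any of 5 single arrays left out. Myelin genes did not pass (adjusted p = 0.43), nor did endothelial (0.57), mural and fibroblast (0.57) or choroid plexus and ependymal markers (0.23), although Mecp2-null replicate 2 had a choroid plexus list mean of 0.84.

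Transmitter-related lists did not pass as groups in the striatum, yet single members stood out when adjusted over the list alone. Of the interneuron markers (adjusted p = 0.30), the cholinergic genes Chat and Slc18a3 stood at -0.38 ± 0.09 and -0.39 ± 0.12, with list-wise adjusted p of 0.024 and 0.049. Without the 2 arrays high in cortical markers they stood at -0.25 and -0.23, and Drd3, given next, at 0.76. Of the monoamine genes (adjusted p = 0.34), the dopamine receptor Drd3 stood at 1.03 ± 0.18, with an adjusted p of 0.0027 over the list and 0.053 over all genes, and the serotonin receptor Htr4 at 0.30 ± 0.07. Of the 18 glutamate receptor genes (adjusted p = 0.10), 4 passed downward and 1 upward over the list alone, among them Grin2c (-0.25 ± 0.06) and Gria4 (-0.21 ± 0.06). GABA receptor and handling genes had 0 such members (adjusted p = 0.23). Genes linked to MeCP2 in earlier work did not pass as a list (adjusted p = 0.15), Irak1 being its called member. The lists for clock genes (0.59), interferon response (0.52), glucocorticoid response (0.73), chaperones (0.23), respiratory chain (0.21), cholesterol synthesis (0.33), fatty acid synthesis (0.18), methyl-DNA machinery (0.79) and genes flanking Mecp2 (0.64) had the adjusted p given after each. Median and mean differed in sign for the glucocorticoid, monoamine, mural and flanking lists.

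The 8 list calls in the striatum need to be read beside chance. Of 100 splits of the 10 arrays, 31 called as many lists at the preset correlation, and 0 lists were called with an estimated correlation. The 57 probe sets were not matched in this way, since the highest of the other splits called 1. For single lists, 4 splits reached the p of precursor markers, 5 of microglia, 12 of cortical, 15 of activity-regulated and 17 of thalamic genes. The numbers were 26 for proliferation genes, 33 for astrocyte and 41 for general medium spiny neuron markers. Among uncalled lists they ran from 2 (genes linked to MeCP2) to 94 (glucocorticoid response). The real split is included and nothing was adjusted over lists.

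In the liver, 63 probe sets were called between Mecp2-null and wild type, 24 higher and 39 lower in Mecp2-null, and by larger amounts. Among genes with their own probe set, the largest fall was in Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway, from 12.11 ± 0.22 to 8.62 ± 0.56 (SD, n = 5; 11.2-fold, adjusted p = 0.00047). The major urinary protein gene Mup3 changed by -3.13 ± 0.43 (SE; adjusted p = 0.019), the complement component C6 from 11.34 ± 0.19 to 8.82 ± 0.51 (adjusted p = 0.0017), Susd4 by -2.15 ± 0.27 and the adipokine gene Serpina12 from 7.44 ± 0.36 to 5.44 ± 0.13 (SD; adjusted p = 0.0010). Scara5 (-1.57), Tmeff2 (-1.52), Dpy19l3 (-1.35), Ces4a (-1.04), Tuft1 (-1.04), Gvin1 (-0.97) and the fibroblast growth factor receptor gene Fgfr1 (-0.90) were lower too. The fatty acid translocase Cd36 rose from 8.09 ± 0.25 to 10.10 ± 0.40 (4.04-fold, adjusted p = 0.0027), the lipoprotein receptor Vldlr by 1.90 ± 0.19, the peroxisomal transporter Abcd2 by 2.38 ± 0.20 (5.21-fold, adjusted p = 0.0014), the acyl-CoA thioesterase Acot3 by 2.18 ± 0.19 and the nuclear receptor Pparg by 0.94 ± 0.16. The cytochrome Cyp2b10 rose by 2.27 ± 0.35, the organic anion transporter Slco1a4 by 1.45 ± 0.22, and the glutathione transferases Gstt3 by 1.48 ± 0.24 and Mgst3 by 0.95 ± 0.15. Atp6v0d2 (1.36), Tox (1.25) and Robo1 (0.80) completed the rises. Larger rises, of 4.81 and 5.43 log2 units, were in 1 probe set unnamed here and 1 with several symbols. In each of the 24 genes all 5 Mecp2-null arrays lay beyond all wild-type arrays, again after selection on the same arrays. Mup3, Cyp2b10, Acot3 and Gstt3 belong to families with close paralogs, and cross-hybridisation was not tested.

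**Figure D3:**
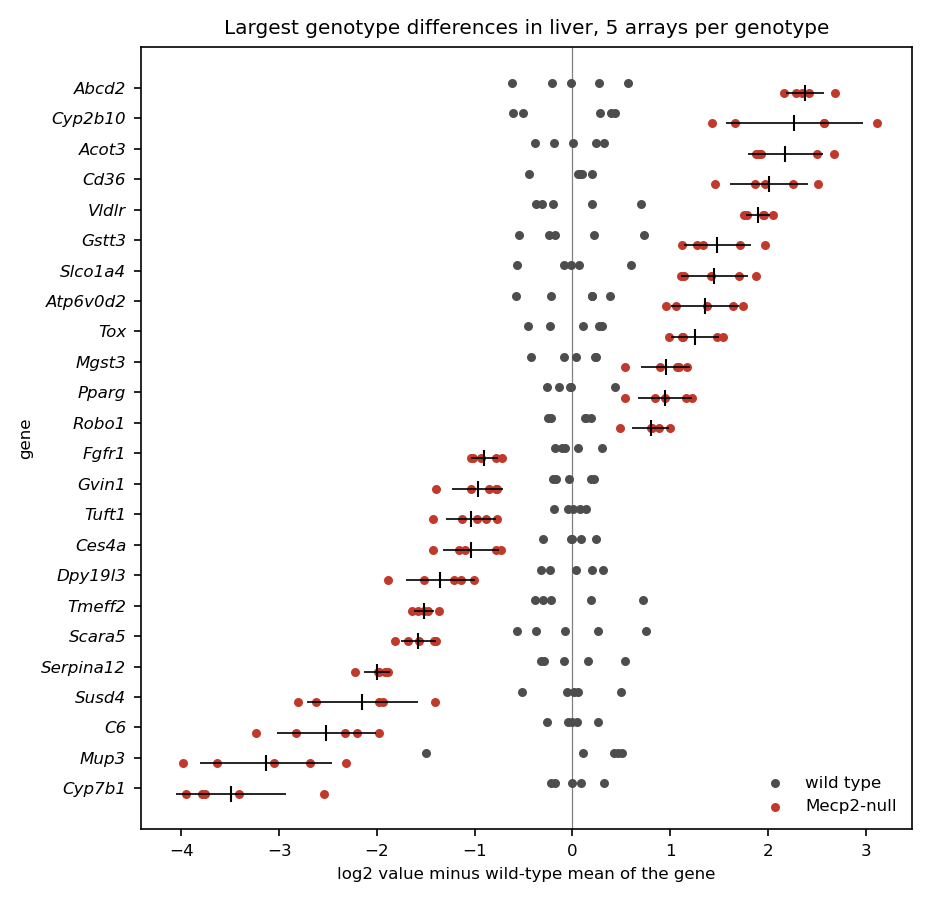
Log2 values of the 24 named liver genes, each minus the wild-type mean of that gene, for 5 wild-type arrays (grey) and 5 Mecp2-null arrays (red), with the Mecp2-null mean and SD in black. The changes run from 2.38 for Abcd2 to -3.49 for Cyp7b1, over a wider scale than in the striatum.

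Of the 63 probe sets, 50 had 1 symbol, 8 had several and 5 were unnamed here. The median absolute change was 0.83 log2 units, and 24 passed 2-fold. At an unadjusted p under 0.05 there were 2335, against 1167 by chance. The count lay between 23 and 92 with any 1 array left out, and was 23 without wild-type replicate 4 and 92 without Mecp2-null replicate 5. It was 505 (275 higher, 230 lower) in 1 fit to all 20 arrays, 120 without dim probe sets and 21 with the replicate number as a block. Of 27 called genes named for the liver, 12 stayed called with each array left out, including Cyp7b1, C6, Serpina12, Abcd2, Acot3, Cd36 and Vldlr, while Mup3, Scara5, Dpy19l3, Ces4a, Gvin1, Irak1, Cyp2b10, Gstt3, Slco1a4, Atp6v0d2, Tox, Mgst3, Pparg, Robo1 and Srebf2 did not, and 9 of the 27 stayed called in every alternative tried. The other splits of the 10 arrays called at most 1 probe set.

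Lists of genes that differ between the sexes in mouse liver shifted in the Mecp2-null males, male-biased genes down and female-biased genes up. No female liver was measured, so the shift could not be set against a female level. Of the listed genes, 9 of 23 male-biased and 11 of 21 female-biased ones were measured. All 9 measured male-biased genes were lower (median -2.20, camera adjusted p = 1.3e-19, and 0.027 with an estimated correlation). Of these, 5 were called over all genes and 9 passed when adjusted over the list alone, led by Cyp7b1, C6, Susd4 and Mup3. All 11 measured female-biased genes were higher (median 1.57, adjusted p = 1.8e-15, and 0.027 with an estimated correlation). Of these, 3 were called over all genes, Abcd2, Acot3 and Tox, and 9 passed over the list alone. Each of the 5 Mecp2-null livers showed the shift, with male-biased list means between -2.78 and -1.23 and female-biased means between 1.03 and 2.15, against -0.24 to 0.17 and -0.23 to 0.31 in wild type. These 2 lists kept their calls in each alternative tried. The Y-linked genes Kdm5d and Eif2s3y, chosen after the shift was seen, were present alike in both genotypes, at 7.71 ± 0.13 and 7.76 ± 0.11 for Kdm5d in wild-type and Mecp2-null liver and at 9.55 ± 0.29 and 9.39 ± 0.10 for Eif2s3y. The growth hormone and IGF axis did not pass as a list (adjusted p = 0.77), with Igfals, the IGF-binding acid-labile subunit, at -0.37 ± 0.09 and Igf1r at 0.17 ± 0.05, both past 0.05 over the list alone.

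**Figure D4:**
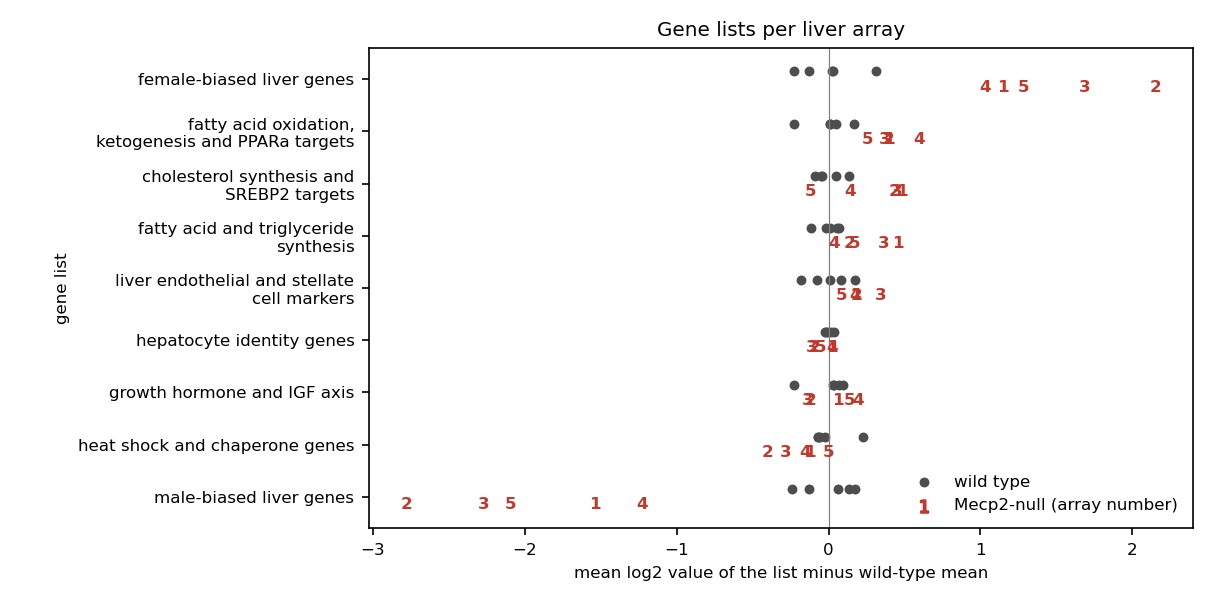
Mean log2 value of 9 gene lists in each liver array, minus the wild-type mean; grey points are the 5 wild-type arrays and red digits the 5 Mecp2-null arrays by replicate number. Male-biased genes lie between -2.78 and -1.23 and female-biased genes between 1.03 and 2.15 in the Mecp2-null livers, while hepatocyte identity genes lie between -0.11 and 0.02.

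Lipid metabolism lists rose in Mecp2-null liver at the preset correlation. Cholesterol synthesis and SREBP2 target genes were higher in 16 of 18 (median 0.23, adjusted p = 2.4e-07, and 0.30 with an estimated correlation). The regulator Srebf2 itself rose by 0.43 ± 0.07 (adjusted p = 0.043), a call kept in 1 of 10 fits with an array left out and lost with median-centred arrays and with a block, and 5 genes passed over the list alone. The list mean of replicate 5 was -0.12, below all wild-type arrays. Fatty acid and triglyceride synthesis genes were higher in 18 of 19 (median 0.18, adjusted p = 2.3e-07, and 0.28 with an estimated correlation), 8 of them past 0.05 over the list alone, led by the elongase Elovl5 (0.55 ± 0.10) and Pnpla3 (0.36 ± 0.09). Fatty acid oxidation, ketogenesis and PPARα target genes were higher in 13 of 19 (median 0.16, adjusted p = 2.8e-05, and 0.30 with an estimated correlation), with Cd36 called and 8 past 0.05 over the list alone. Endothelial and stellate cell markers were higher in 19 of 19 genes by little (median 0.17, adjusted p = 6.5e-05, and 0.27 with an estimated correlation), none of them passing even over the list alone, with Dcn at 0.26 ± 0.10. Chaperone genes fell (16 of 19 lower, median -0.18, adjusted p = 0.0036, and 0.30 with an estimated correlation), with Pdia6 at -0.29 ± 0.10.

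Other hepatic lists did not pass. Hepatocyte identity genes had a median of 0.02 (adjusted p = 0.82), and the markers of Kupffer and other immune cells (0.77), cholangiocytes (0.86) and adipose or pancreatic tissue (0.77) gave the adjusted p shown. Bile acid genes moved both ways, with Cyp7b1 down and Slco1a4 up (adjusted p = 0.77). Of the xenobiotic cytochromes and their regulators Cyp2b10 was called (list adjusted p = 0.77). The remaining lists were gluconeogenesis and amino acid catabolism (0.17), acute phase (0.77), interferon response (0.77), proliferation (0.86), clock (0.54), glucocorticoid response (0.23), respiratory chain (0.99), methyl-DNA machinery (0.17), genes linked to MeCP2 earlier (0.17) and genes flanking Mecp2 (0.32). In the gluconeogenesis list the coactivator Ppargc1a stood at 1.05 ± 0.25, past 0.05 over the list alone. Of the flanking genes the creatine transporter Slc6a8 (-0.56 ± 0.07, adjusted p = 0.0089) and Irak1 (-0.34 ± 0.05, adjusted p = 0.019) were lower. Median and mean differed in sign for the xenobiotic, interferon, flanking and hepatocyte lists. Of 100 splits of the liver arrays, 23 called at least the 7 lists seen here, whereas the p of the male-biased and of the female-biased list was reached by 1 split each, the real one. For the other called lists, 2 splits reached the p of endothelial and stellate markers and 3 that of fatty acid oxidation. Fatty acid synthesis gave 6, cholesterol synthesis 10 and chaperones 17, the real split included and without adjustment over the lists.

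The genotype effect differed between the tissues for 170 probe sets, 86 with the higher difference in striatum and 84 in liver. Among named genes the largest were liver changes, with striatal differences between -0.25 and 0.19. Cyp7b1 differed by 3.43 ± 0.27 (SE; adjusted p = 1.7e-06), Mup3 by 3.18 ± 0.47, C6 by 2.54 ± 0.23, Susd4 by 2.34 ± 0.29 and the elongase Elovl3 by 2.20 ± 0.45. Abcd2 (-2.63 ± 0.23), Cyp2b10 (-2.32 ± 0.38), Acot3 (-2.28 ± 0.22), the ω-hydroxylase Cyp4a14 (-2.28 ± 0.49) and Cd36 (-2.14 ± 0.21) led the other way. Elovl3 and Cyp4a14, at -2.29 and 2.38 in liver, were not called in the liver comparison itself. Elovl3 stayed called in 16 and Cyp4a14 in 4 of 20 fits with 1 array left out, and both lost the call without the 2 striatal arrays high in cortical markers (2.17 and -2.30, adjusted p = 0.091 and 0.10), where the differences stayed about as large, and with a block. The interaction passed for 33 of the 57 striatal and 55 of the 63 hepatic probe sets. It covered 83 probe sets called in neither tissue, and the absolute change was larger in liver for 118 of the 170. The interaction fit takes 1 spread per probe set over both tissues, and in such a fit the hepatic genotype count was 505 against 63. How many of the 83 calls rest on the shared spread was not tested. Because the livers came from the same animals, a fit with the animal as a block was made as well. It takes equal replicate numbers as 1 animal, which the labels do not say, and called 82. Without the 2 striatal arrays high in cortical markers 112 were called.

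The tissues shared 2 called probe sets, where independent calls would give 0.154 (Fisher's exact test, two-sided, p = 0.010). Irak1 was one and moved in opposite directions, up by 1.11 ± 0.07 in striatum and down in liver (-0.34 ± 0.05), a difference of 1.46 ± 0.08 (interaction adjusted p = 4.4e-09). Its striatal call held in each of 10 fits with an array left out and its liver call in 3 of 10, with liver values between -0.36 and -0.33 over all alternatives. The other, probe set 7017610, is unnamed here and fell in both, at -0.94 ± 0.07 in striatum and -0.59 ± 0.08 in liver. Its number follows that of Irak1 (7017609), so it may lie at the targeted locus or measure Mecp2 itself, which was not tested. The 2 shared calls therefore give no evidence of a shared response away from that locus. Per direction, independent calls would give 0.0451 shared falls and 0.0309 shared rises. Across all probe sets the 2 tissues' changes correlated at 0.0692 (Pearson) and 0.0719 (Spearman), where probe sets are not independent replicates. The number of shared calls fell to 0 without wild-type liver replicate 2 or Mecp2-null liver replicate 1.

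**Figure D5:**
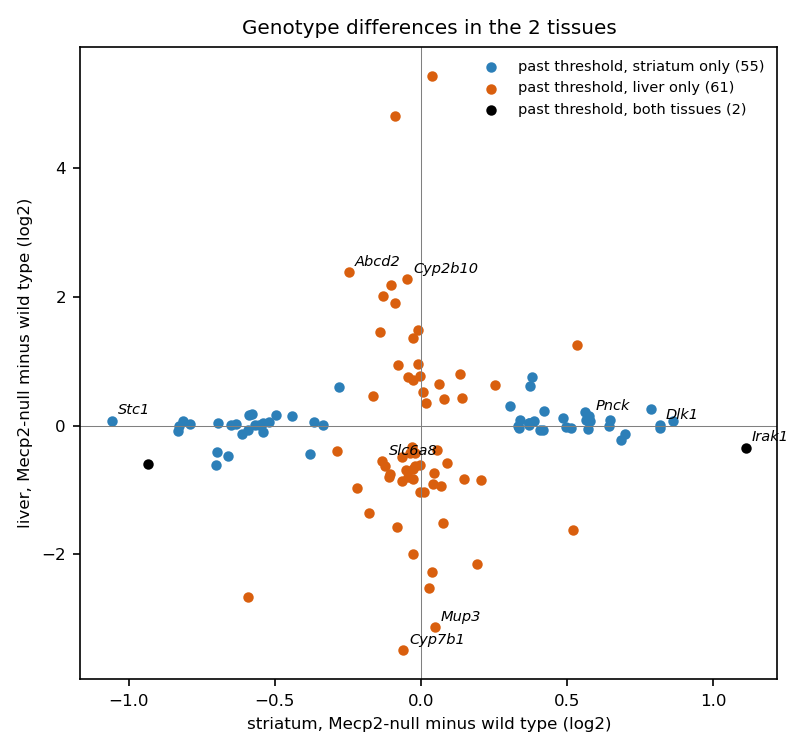
Genotype differences (Mecp2-null minus wild type, log2) in striatum (x axis) and liver (y axis) for each probe set called in at least 1 tissue, coloured by the tissue in which it was called. Changes of one tissue mostly lie near 0 in the other, and Irak1 lies at 1.11 in striatum and -0.34 in liver.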

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

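The splits of the arrays, for which 100 were drawn in each comparison, were planned before their results were seen, and the tests of cortical tissue, sex, hepatocyte share and probe sequence were chosen after the patterns were seen.

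The counts of probe sets were matched by no other split. In each, 1 of 100 splits, the real one, reached the observed count. The real striatal count was 57 against at most 1 in the other splits, the hepatic one 63 against 1, the interaction 170 against 98 and the comparison of wild-type tissues 19622 against 0. Chance cannot be excluded for the counts of gene lists called with the preset correlation. In the striatum 31 of 100 splits reached the 8 lists seen, with up to 12 in another split, and in the liver 23 of 100 reached the 7 lists seen, with up to 11.

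The first pattern is the rise of cortical excitatory neuron markers in Mecp2-null striatum. Cortical tissue taken along in replicates 4 and 5 is a candidate explanation, since medium spiny neuron markers were lowest in the same 2 arrays. Replicates 1 and 2, with cortical list means of 0.40 and 0.25, also lay above all wild-type arrays (at most 0.17). Without replicates 4 and 5 the mean shift of the list fell from 0.65 to 0.17 log2 units and its camera adjusted p was 0.099. Because replicates 4 and 5 were picked for these same markers, that fall had to occur and does not decide the question. For the immediate early and activity-regulated genes the arrays are too few to decide, since their list mean without these 2 arrays differed by 0.19 ± 0.24 log2 units (SE), and 15 of 100 splits gave that list a p as small as the real one. As the whole account of the probe sets called in the striatum, such tissue is argued against by the 53 called without the 2 arrays, 33 of them among the 57, while 21 of the 57 stayed called with the cortical marker mean as a covariate. Whether MeCP2 loss itself changes cortical or activity genes in these animals stays open, as do differences in dissection or handling, which no label records.

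The second pattern is the fall of male-biased and the rise of female-biased genes in Mecp2-null liver. Female animals or arrays of the wrong sex are argued against by the Y-linked genes, whose mean differed by -0.0581 ± 0.0901 log2 units (SE) between the genotypes. A lower share of hepatocytes cannot alone account for the female-biased genes, which hepatocytes also make and which rose by a median of 1.57. That rise is part of the pattern, so it is no separate test. Hepatocyte identity genes, a separate list, had a median of 0.02 (camera adjusted p = 0.82). Their list means lay between -0.11 and 0.02 in the Mecp2-null livers, far from the male-biased median of -2.20. A hypothesis that stays open is that the male pattern of growth hormone release, which sets the sex bias of mouse liver, may be altered in symptomatic Mecp2-null males, and low weight or illness could act in the same way. The design holds no measure of hormones, food intake or weight, so these were not tested.

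The third pattern is Irak1, up in striatum and down in liver, the liver call being lost in 7 of 10 fits with an array left out. A sequence difference under its probes, carried with the Mecp2-null allele, would shift both tissues the same way. It cannot alone account for the difference of 1.46 ± 0.08 between them (SE, interaction adjusted p = 4.4e-09). The opposite signs define the pattern, so they are no separate test, and a contribution of such a sequence difference in either tissue stays open. Cortical tissue in replicates 4 and 5 is argued against, since the striatal rise was 1.19 ± 0.06 without them. The list of 22 measured genes flanking Mecp2 passed in neither tissue (adjusted p = 0.64 in striatum and 0.32 in liver), and it held 2 called genes, Irak1 and Slc6a8, against 0.139 for independent calls, a count prompted by Irak1 itself, so no test of it is given. An effect of the targeted locus or of flanking DNA on Irak1, and on Slc6a8 and Pnck 12 and 13 measured genes from Mecp2 on the same side, may contribute but was not tested, and these data do not separate it from loss of the protein.

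Single arrays stood apart from the rest of their group in 6 of 126 groups examined, where chance gives about 1 in 20. The gap to the nearest array, as a share of the range, was 0.716 for Cdh4 in wild-type striatal replicate 2 (high) and 0.764 for Efna5 in wild-type striatal replicate 4 (low). In wild-type liver it was 0.786 for Cd36 in replicate 1 (low) and 0.798 for Mup3 in replicate 3 (low, at 7.29 against 8.89 or above). It was 0.710 for the mean of proliferation genes in wild-type striatal replicate 5 (high) and 0.842 for the mean of chaperone genes in wild-type liver replicate 1 (high).

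Genotype effects that differed between tissues by the interaction test were largest for Cyp7b1 (3.43), Mup3 (3.18), C6 (2.54), Susd4 (2.34) and Elovl3 (2.20), and for Abcd2 (-2.63), Cyp2b10 (-2.32), Acot3 (-2.28), Cyp4a14 (-2.28) and Cd36 (-2.14). Of these, Cyp4a14 kept its call in 4 and Elovl3 in 16 of 20 fits with 1 array left out, and both lost it without the 2 striatal arrays high in cortical markers (-2.30 and 2.17, about as large; adjusted p = 0.10 and 0.091). Neither of them was called in the liver comparison itself.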

How the results depend on the processing

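All alternatives except the 2 that concern cortical markers were chosen before the data were examined. No gene called in the text changed direction in any of them. The uncalled myelin genes Ugt8a and Mag did with the cortical marker mean as a covariate, to 0.0637 and 0.0256, and the cause was not tested. The striatal count of 57 was 143 without dim probe sets and 99 with 1-symbol probe sets, where fewer probe sets were tested, 90 after repeated quantile normalization, 99 in 1 fit to all 20 arrays, 27 with the cortical covariate, and 28 to 54 with each array left out. The hepatic count of 63 was 120 without dim probe sets, 100 with 1-symbol probe sets, 505 in 1 fit to all 20 arrays, and 23 to 92 with each array left out. The interaction count of 170 was 273 with array weights, 112 without the 2 arrays high in cortical markers, where fewer arrays were used, and 115 to 268 with each array left out, the highest without Mecp2-null liver replicate 5. The count between wild-type tissues was 10251 without dim probe sets, where fewer were tested, and 19221 to 19657 with each array left out. Lists called in the striatum numbered 5 after repeated quantile normalization and 0 with an estimated correlation, and 6 to 11 with each array left out. General medium spiny neuron, astrocyte and proliferation lists were lost after the quantile normalization. In the liver they numbered 2 with an estimated correlation, and 7 to 8 with each array left out. Probe sets called in both tissues numbered 4 without dim probe sets, 7 in 1 fit to all 20 arrays, 4 with array weights and 1 with 1-symbol probe sets, and 0 to 4 with each array left out. Where no reason is given, the cause was not tested.

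With the replicate number as a block the striatal count was 10, the hepatic 21, the interaction count 82 and the shared count 0, and the block uses up degrees of freedom. Whether equal numbers mark paired arrays stayed undecided, since paired arrays need not correlate across probe sets. Deviations of same-numbered wild-type and Mecp2-null arrays correlated between -0.13 and -0.01 in striatum and between -0.09 and 0.03 in liver, and those of same-numbered striatal and hepatic arrays between -0.04 and 0.16. An array correlated best with its own number in 0, 0 and 3 of 5, 5 and 10 cases. These 3 were Mecp2-null replicates 3, 4 and 5 between striatum and liver, at 0.07, 0.16 and 0.08. Signal over background is not known here, so changes of dim probe sets are the least certain.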

Other observations

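Of 6 terminal complement genes, chosen after their values were seen, 3 fell in Mecp2-null liver. Besides C6 (-2.52 ± 0.22, SE), C9 went from 11.98 to 11.13 (-0.85 ± 0.10, adjusted p = 0.0093) and C8a from 12.05 to 11.36 (-0.69 ± 0.10, adjusted p = 0.027). C8b stood at -0.59 ± 0.11 (adjusted p = 0.073), Hc, which encodes C5, at -0.24 ± 0.08 (adjusted p = 0.33) and C8g at -0.02 ± 0.08 (adjusted p = 0.96), with levels of 12.31 in wild type and 12.29 in Mecp2-null liver.

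Some genes of cell adhesion or axon guidance were chosen because they were called in the striatum, and no enrichment was tested. Beside Cdh4 and Efna5, the cadherin Cdh22 rose by 0.34 ± 0.05 (SE, adjusted p = 0.035) and the teneurin Tenm3 by 0.38 ± 0.05 (adjusted p = 0.024), while the guidance receptor Robo3 fell (-0.59 ± 0.05, adjusted p = 0.0012). The difference from the liver passed the interaction test for Robo3 (adjusted p = 0.0017), Cdh4 (0.0080) and Efna5 (0.030), and not for Cdh22 (0.15) or Tenm3 (0.48).

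Pnck, a calmodulin kinase gene on the X chromosome, lies 13 measured genes from Mecp2 and next to Slc6a8 (12), on the side of Irak1. It rose by 0.58 ± 0.07 in striatum (SE, adjusted p = 0.013), a call lost without the 2 arrays high in cortical markers (0.54, adjusted p = 0.083), with the cortical covariate and with the block, and stood at 0.15 ± 0.10 in liver (adjusted p = 0.69). Slc6a8 stood at -0.13 ± 0.04 in striatum (adjusted p = 0.31) and fell in liver, and the 2 genes were not compared by a test.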
